A study of Homo sapiens with 4 samples.

How the data were processed

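Total RNA of OVCAR3 cells was sequenced as 4 libraries. OVCAR3 is an established human cell line of high-grade serous ovarian carcinoma. Per the labels, 3 libraries came from cells in which the pseudogene transcript ANAPC1P2 had been knocked down with a short hairpin RNA (KD, called Set 1, 2 and 3 there and KD 1, 2 and 3 here) and 1 library came from wild-type cells (WT). Nothing in the labels says whether the 3 knockdown sets were separate cultures, separate hairpins or repeats of one preparation, so each p-value measures the spread between these libraries, which may be technical. None of the 4 libraries is labelled as a control with a non-targeting hairpin. Effects of carrying a hairpin therefore cannot be separated from those of losing ANAPC1P2. Per the labels' protocols, ribosomal RNA was depleted (KAPA RiboErase), the remaining RNA was fragmented with heat, and libraries were made with dUTP in the second cDNA strand, which marks the strand of origin. Libraries of this type keep unspliced, nuclear and non-polyadenylated RNA.

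Per the submitters' processing notes, STAR 2.7.11b, featureCounts 2.0.6 and DESeq2 were used with the genome build hg38. The order of the steps, the annotation release, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. The deposited signal values are normalized read counts per gene, 1 file per library with 62696 gene rows. Within each library, 100% of the deposited values were whole multiples of 1 step, to within 0.001 reads, so the values are whole read counts divided by 1 factor per library, and the reads were recovered. The factors were 1.0551, 1.2869 and 0.8995 for KD 1, 2 and 3 and 0.9003 for WT. A median-of-ratios calculation on these 4 libraries alone gave 1.0, 1.2435 and 0.8743 for KD and 1.0512 for WT, so the deposited factors are not those of this calculation. How the authors computed them is not given in the sources used here.

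The recovered depth was 48443589, 56216398 and 42871815 counted reads in KD 1, 2 and 3 and 27868718 in WT. A count of 3 reads, the floor used for a gene with 0 reads, equals 0.926 normalized counts over the 3 knockdown libraries together and 3.33 in WT. Where a gene had 0 reads in a group, the fold is a lower bound against this floor. Ratios from few reads carry an exact 95% conditional binomial interval and single counts an exact 95% Poisson interval. The libraries carry no molecular identifiers in the sources used here, so intervals and floors cover counting error only. Gene types, positions and exonic lengths came from GENCODE 29 on GRCh38, where 92.9% of all gene identifiers and 95.1% of the tested ones were found. Positions of ANAPC1P2 were also taken from RefSeq on GRCh38.p14.

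The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), for the 23344 genes with a mean of at least 10 normalized counts over the 4 libraries, of which 14464 are protein-coding. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread is estimated from the 3 knockdown libraries only, and the lone wild-type library is assumed to vary like them. Differences are on the log2(value + 1) scale and understate the change of low genes. On simulated data with the means and library sizes of this comparison, limma recovered 76 of 100 genes changed 2-fold and 87 of 100 genes changed 4-fold, with 18 false calls among 23144 unchanged genes. Changed genes were drawn from those with a mean of at least 50 normalized counts, so recovery of lower genes was not simulated. The simulation gave the lone library the same spread as the others, so it says nothing about an atypical wild-type library. edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads were alternatives. They recovered 76 and 75 of the genes changed 2-fold and 89 and 87 of those changed 4-fold.

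In total, 33 gene lists were fixed before the data were examined and tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation stands beside it. That form of the test has only the few residual degrees of freedom of these libraries. A list could hardly be called by it whatever its genes did, so a missing call there decides nothing. Counts of list members are given over all genes tested, and those adjusted over the list alone were the same in the lists described unless given beside them. The genes named in the text follow a rule also fixed before the data were examined. They are ANAPC1P2, ANAPC1 and its other pseudogenes; the 12 protein-coding genes with the largest rise and the 12 with the largest fall, among genes past the threshold with a log2 difference of at least 1, a mean of at least 100 normalized counts in the higher group and all 3 knockdown libraries on the same side; and, for lists with an adjusted p under 0.05 or at least 5 called members, up to 4 called members with a mean of at least 20 normalized counts and called members that went against the list. Some genes that this rule selects are not reported here. Measured neighbours of ANAPC1P2 within 1 Mb were also planned, and only some of them are given. Any other gene is said to have been chosen after its values were seen.

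Other pseudocounts, filters, scalings, variance models and tools and the removal of each knockdown library were planned as alternatives. The scaling by median of ratios of these 4 libraries, a test of protein-coding genes only, thinning of the knockdown reads to the wild-type depth and the comparison of list medians with 10000 random lists matched on expression and exonic length were added after seeing the data. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.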

Results

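RNA-seq libraries were compared between OVCAR3 ovarian carcinoma cells carrying a hairpin RNA against ANAPC1P2 (n = 3 libraries) and wild-type OVCAR3 cells (n = 1 library). The question was which transcripts differ between cells with this hairpin and wild-type cells. ANAPC1P2 is a pseudogene copy of ANAPC1, which encodes the largest subunit of the anaphase-promoting complex (APC/C), the ubiquitin ligase that drives exit from mitosis. In genes, 48443589, 56216398 and 42871815 reads were counted in KD 1, 2 and 3 and 27868718 in the wild-type library (WT). Despite its lower depth, the wild-type library had reads in 36832 genes, against 31661, 32823 and 31014 in the knockdown libraries. Values below are normalized read counts as deposited, given as mean ± SD over the 3 knockdown libraries, and the wild-type value has no replicates. No pair of libraries agreed within sampling noise. Pearson's r of log2 values across genes was 0.983 to 0.987 between knockdown libraries and 0.865 to 0.889 between knockdown and wild type, where genes are not independent replicates.

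The targeted transcript was rare in all 4 libraries. ANAPC1P2 (ENSG00000285793) lies on the minus strand of chromosome 2 at 87030675 to 87076429 in GENCODE 29 (GRCh38), where it is a processed transcript with 11 exons, and RefSeq places the pseudogene at 87030675 to 87076413. It had 0, 11 and 8 reads in KD 1, 2 and 3 and 14 reads in WT, or 0, 8.55 and 8.89 normalized counts against 15.6. The knockdown group as a whole stood at 37.7% of the wild-type rate (95% exact counting interval 17.9% to 81.3%). Without KD 1, which had no read, it stood at 55.9% of the wild-type rate with an interval of 26.6% to 120.5%, which includes no difference. The gene was under the expression filter and was not tested. Its log2 difference of -1.86 was close to the median of -1.76 over 4981 other genes that are not protein-coding and had a similar mean level, and 47.2% of these genes were at or below it. A further ANAPC1P2 identifier (ENSG00000231259) had 0 reads in all 4 libraries. It lies within the first one on the same strand (87031815 to 87052992). Reads in any exon common to both may have been split or dropped by the counting. Reads shared between ANAPC1 and its near-identical pseudogenes may be split or dropped by the counting, so these values are uncertain.

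**Figure D1:**
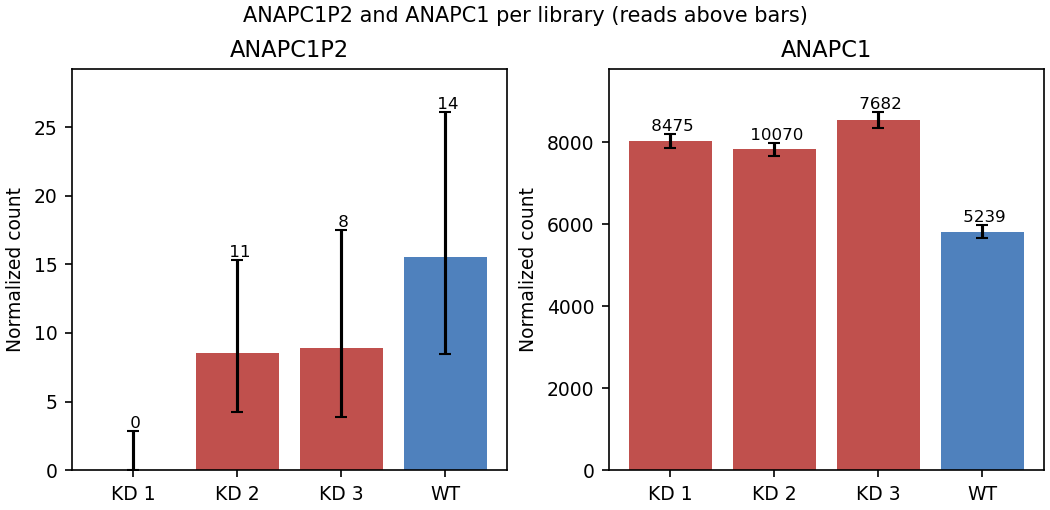
Normalized counts of ANAPC1P2 (left) and ANAPC1 (right) in each library, on axes that start at 0. Bars are single libraries (red, knockdown; blue, wild type), error bars are exact 95% Poisson intervals of the read count (for 0 reads, the floor of 3 reads), and the read count stands above each bar. ANAPC1P2 had 0 to 11 reads in knockdown and 14 in wild type, and ANAPC1 was at 8133 ± 368 against 5819, a direction that turns when library totals are made equal.

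The parent gene ANAPC1 (chromosome 2, 111766231 to 111884193 in RefSeq) had 8133 ± 368 normalized counts in knockdown and 5819 in WT, a log2 difference of 0.48 with the deposited scaling (limma adjusted p = 6.61e-03). As a share of all reads it was slightly lower in knockdown, at 174.9, 179.1 and 179.2 RPM against 188.0 in WT, and the log2 difference with equal library totals was -0.08. ANAPC1P1 had 22.3 ± 4.93 normalized counts against 31.1 in WT and was not called (log2 difference -0.48, adjusted p = 0.404). ANAPC1P4 and ANAPC1P6 had 4 and 7 reads over the knockdown libraries and 1 and 4 reads in WT, and ANAPC1P3 and ANAPC1P5 had none.

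Among genes higher in knockdown, MFAP5, which encodes a microfibril-associated glycoprotein, had 437 ± 233 normalized counts and no read in WT (at least 131.2-fold higher). EDN2, the vasoactive peptide endothelin-2, and the transcription factor gene TFAP2B also had no read in WT, and were at least 70.2-fold and 51.04-fold higher. The glutathione transferase genes GSTA1 and GSTA2 stood at 310 ± 38.4 and 193 ± 17.2 against 4.44 and 2.22 in WT. GSTA2, with 2 wild-type reads, was 86.4-fold higher with a counting interval of 23.8 to 715. These genes are close paralogs, so reads may be shared between them. The cancer-testis gene XAGE2 stood at 1388 ± 171 against 27.8, and the phosphatase gene PTPRR at 2655 ± 754 against 69.97. The protease inhibitor gene CSTA was 36.7-fold higher and RELN, which encodes the matrix protein reelin, 22.4-fold. ANKRD30B stood at 119 ± 41.9 against 2.22, and the histone genes H3C1 and H3C8 were 23.4-fold and 22.8-fold higher. Adjusted p for these 12 genes was at most 1.95e-04 (limma), and all 3 knockdown libraries were above WT for each.

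Genes lower in knockdown included several that were abundant in WT and had no read in any knockdown library. The beta-globin gene HBB had 12412 normalized counts in WT and 0 in knockdown (at least 13410-fold lower), and the alpha-globin genes HBA2 and HBA1 had 1735 and 241. The neuronal transcription factor gene NEUROD6 had 2374, the secretory-pathway kinase gene FAM20C 513, FCGR3B, an Fc receptor of neutrophils, 217 and the muscarinic receptor gene CHRM2 192, each with 0 reads in knockdown. FCGR3B has a close paralog, and HBA1 and HBA2 are near-identical copies of each other. The matrix gene THBS2 was 956-fold lower (counting interval 263 to 7910), GAS7 662-fold (257 to 2430), H1-5 497-fold (136 to 4120) and the glutamate receptor gene GRIN2A 159-fold (82.8 to 350). Each of these folds rests on few knockdown reads. Without KD 3, which held all 9 GRIN2A and both H1-5 reads, the genes were at least 344-fold and 239-fold lower, and without KD 1, which held both THBS2 reads, THBS2 was at least 430-fold lower. Without KD 2, which had no read of any of them, the folds were 576 for THBS2, 399 for GAS7, 299.6 for H1-5 and 95.8 for GRIN2A. Adjusted p for each of these genes was at most 3.99e-03 (limma), and all 3 knockdown libraries were below WT. In all, 22 protein-coding genes had at least 100 normalized counts in WT and no read in knockdown, and 3 had a knockdown mean of at least 100 and no read in WT. Because transcripts typical of blood and neural cells were found in the library labelled wild type, and the values do not settle whether its RNA came from OVCAR3 cells only, each of these folds compares the libraries as labelled.

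Genes for cell division were higher in knockdown. Of 40 measured G2/M and mitosis genes, 35 rose and 1 fell, with a median log2 difference of 1.61 (camera adjusted p = 1.44e-11). With an estimated correlation between genes, adjusted p was 0.655 for this list and for each other list of cell division genes given next. MAD2L1, a spindle checkpoint protein, rose from 769 in WT to 6576 ± 748, the mitotic motility receptor HMMR from 1322 to 9698 ± 1129, securin (PTTG1) from 2736 to 14608 ± 1439 and cyclin A2 (CCNA2) from 1637 to 9711 ± 671. NUSAP1, a spindle protein, went against the list at 30.8 ± 10.9 against 116. Of 40 G1/S and DNA replication genes, 37 rose (38 adjusted over the list alone) and 0 fell, with a median of 1.17 (adjusted p = 1.65e-11), among them PRIM1, PCNA, RRM1 and MCM6, 5.88-fold, 5.39-fold, 5.23-fold and 3.46-fold higher. Of 20 genes of the APC/C, its coactivators, its ubiquitin-conjugating enzymes and an inhibitor of it, 16 rose (17 adjusted over the list alone) and 1 fell, with a median of 1.02 (adjusted p = 1.06e-05). The subunit ANAPC13 was 4.32-fold higher, the E2 genes UBE2C and UBE2D1 3.89-fold and 3.46-fold and the coactivator CDC20 3.75-fold, while the subunit ANAPC2 was lower, at 766 ± 65.7 against 1033. Against random protein-coding lists matched on mean expression and exonic length, the G2/M median lay at percentile 99.96. The G1/S and APC/C medians lay at only 91.66 and 86.45 (medians of the matched lists 0.966 and 0.765). With expression alone matched, these 2 lay at 99.9 and 96.1. The G1/S and APC/C rises may therefore be those of genes of like length and level. Replication-dependent histone genes moved apart: 30 of 37 rose, with a median of 2.95 (adjusted p = 6.39e-10), and H1-5, H3C3, H4C9, H4C4 and H2BC3 fell, by factors of 497, 228, 9.94, 7.25 and 5.88. These genes are short and close paralogs of each other.

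Most listed genes of protein and energy production were higher as well. Genes of the hypoxia and glycolysis list went both ways, with ENO2 and PFKFB4, for example, 2.45-fold and 1.58-fold lower. The median of that list lay at percentile 61.56 of random protein-coding lists matched on mean expression and exonic length. Of 48 ribosomal protein genes 47 rose and 0 fell, with a median log2 difference of 1.99 (camera adjusted p = 9.69e-18), among them RPS2, RPL32 and RPS25 at 8.29-fold, 7.58-fold and 6.54-fold. Adjusted p with an estimated correlation was 0.655, as it was for oxidative phosphorylation, the proteasome and glycolysis. Of 42 nuclear-encoded genes of oxidative phosphorylation, 36 rose (37 adjusted over the list alone) and NDUFV2 and NDUFA10 fell, with a median of 1.61 (adjusted p = 8.34e-12). NDUFA4 and NDUFB3, of the respiratory chain, were 7.03-fold and 6.82-fold higher. Of 31 proteasome subunit genes 28 rose and PSMA2 fell, with a median of 1.67 (adjusted p = 1.63e-10), with PSMA4 6.84-fold higher. GAPDH and LDHA, of glycolysis, rose 4.31-fold each, in a hypoxia and glycolysis list in which 19 of 32 genes rose and 6 fell (median 0.61, adjusted p = 7.06e-03, or 0.092 with a mean of at least 50 normalized counts and 0.366 with protein-coding genes only). The 13 mRNAs of the mitochondrial genome had a median of 0.58 and were not called as a list (adjusted p = 0.0964, but 0.036 with TMM, 0.0384 with upper-quartile and 0.0292 with median-of-ratios scaling and 0.0112 with no filter): 7 rose, among them MT-ATP6 and MT-CO3, and MT-CO1 fell. Their median lay at percentile 30.04 of 10000 random protein-coding lists matched on mean expression and at 0.04 of lists matched on exonic length too (median of these 1.73), so it was below that of genes of like length and level.

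Mesenchymal and leukocyte markers were lower in knockdown. Of 35 mesenchymal and matrix genes 24 fell and 6 rose, with a median log2 difference of -1.51 (camera adjusted p = 3.15e-03). That median lay at percentile 0.0 of 10000 random protein-coding lists matched on mean expression (median of these 0.062) and of as many matched on exonic length too (-0.145). With an estimated correlation, this list and the leukocyte list each had adjusted p = 0.655. ZEB1, a repressor of epithelial genes, had 93.3 normalized counts in WT and no read in knockdown (at least 100.8-fold lower), the gelatinase MMP2 stood at 77.4 ± 37.1 against 1608, TGFBI at 33.8 ± 11.9 against 458 and the collagen gene COL5A1 at 2.52 ± 2.28 against 94.4. Of 11 leukocyte markers 10 fell and 0 rose, with a median of -2.15 (adjusted p = 5.94e-03), including LYZ (95.5 in WT, no read in knockdown), SPI1 (13.3 ± 7.13 against 161) and PTPRC (31.01 ± 8.33 against 190). Both medians were the same with genes at 0 set to their bound. With a mean of at least 50 normalized counts, which left 5 leukocyte markers, the leukocyte list lost its call (adjusted p = 0.0512). As for the globin genes, the values of neither list settle whether the RNA labelled wild type came from OVCAR3 cells only. Fibroblast, endothelial and mesothelial markers were not called as lists, with medians of -1.01, -0.92 and -0.32 over 12, 9 and 6 genes (adjusted p = 0.219, 0.364 and 0.984).

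Of 34 epithelial genes 19 rose and 4 fell (median 0.50, camera adjusted p = 4.86e-03, or adjusted p = 0.655 with an estimated correlation), with MAL2 and keratin 18 (KRT18) 4.65-fold and 3.16-fold higher and the adhesion gene CDH1 lower, at 7504 ± 721 against 9666. The median of this list changed sign, to -0.06, with equal library totals. The NF-kB, unfolded protein response, homologous recombination and p53 lists also had adjusted p = 0.655 each with an estimated correlation. Markers of serous ovarian carcinoma went both ways, 14 of 24 higher and 7 lower (adjusted p = 0.177). MUC16, which encodes the tumour antigen CA125, was 15.5-fold lower at 28927 ± 5655 against 458890, while the peptidase gene KLK6 was 11.9-fold higher and the folate receptor gene FOLR1 3.52-fold higher. In the list of NF-kB and inflammatory cytokine genes 14 of 27 rose and 5 fell (median 0.56, adjusted p = 0.0457, median -0.01 with equal totals). The chemokine gene CXCL8 stood at 18008 ± 3925 against 1461, CCL20 and CXCL1 were 12.6-fold and 4.76-fold higher, and IL1B and CCL2 were 5.83-fold and 3.00-fold lower. Counting intervals were 6.97 to 25.4 for CCL20, with 11 wild-type reads, and 3.6 to 9.61 for IL1B. Of 30 genes of the unfolded protein response and ATF4 pathway 21 rose and 2 fell (median 0.68, adjusted p = 4.68e-04), including TRIB3, PSAT1 and MTHFD2. Of 34 genes of homologous recombination and the Fanconi pathway 25 rose and 5 fell (median 0.71, adjusted p = 4.19e-04). RAD51AP1 and CHEK1 were 4.46-fold and 3.67-fold higher, and FANCC and RAD51B fell to 1287 ± 33.5 from 2559 and to 780 ± 42.7 from 1444. The p53 target list was called at adjusted p = 0.0445 with 13 of 28 genes higher and 4 lower. Its best-known member CDKN1A, the cell cycle inhibitor p21, fell, at 32.5 ± 3.73 against 181, as did TP53INP1, while CCNG1 and TRIAP1 rose, and the list median of 0.41 became -0.165 with equal totals. The p53 list lost its call with equal totals (adjusted p = 0.267), a mean of at least 50 normalized counts (0.428), thinned knockdown reads (0.0585) and protein-coding genes only (0.888), and the NF-kB and epithelial lists lost theirs with equal totals (0.265 and 0.13), that mean (0.323 and 0.167) and protein-coding genes only (0.891 and 0.411). The homologous recombination list lost its call with protein-coding genes only (0.104), and the unfolded protein response list with those (0.123) and with that mean (0.0512).

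**Figure D2:**
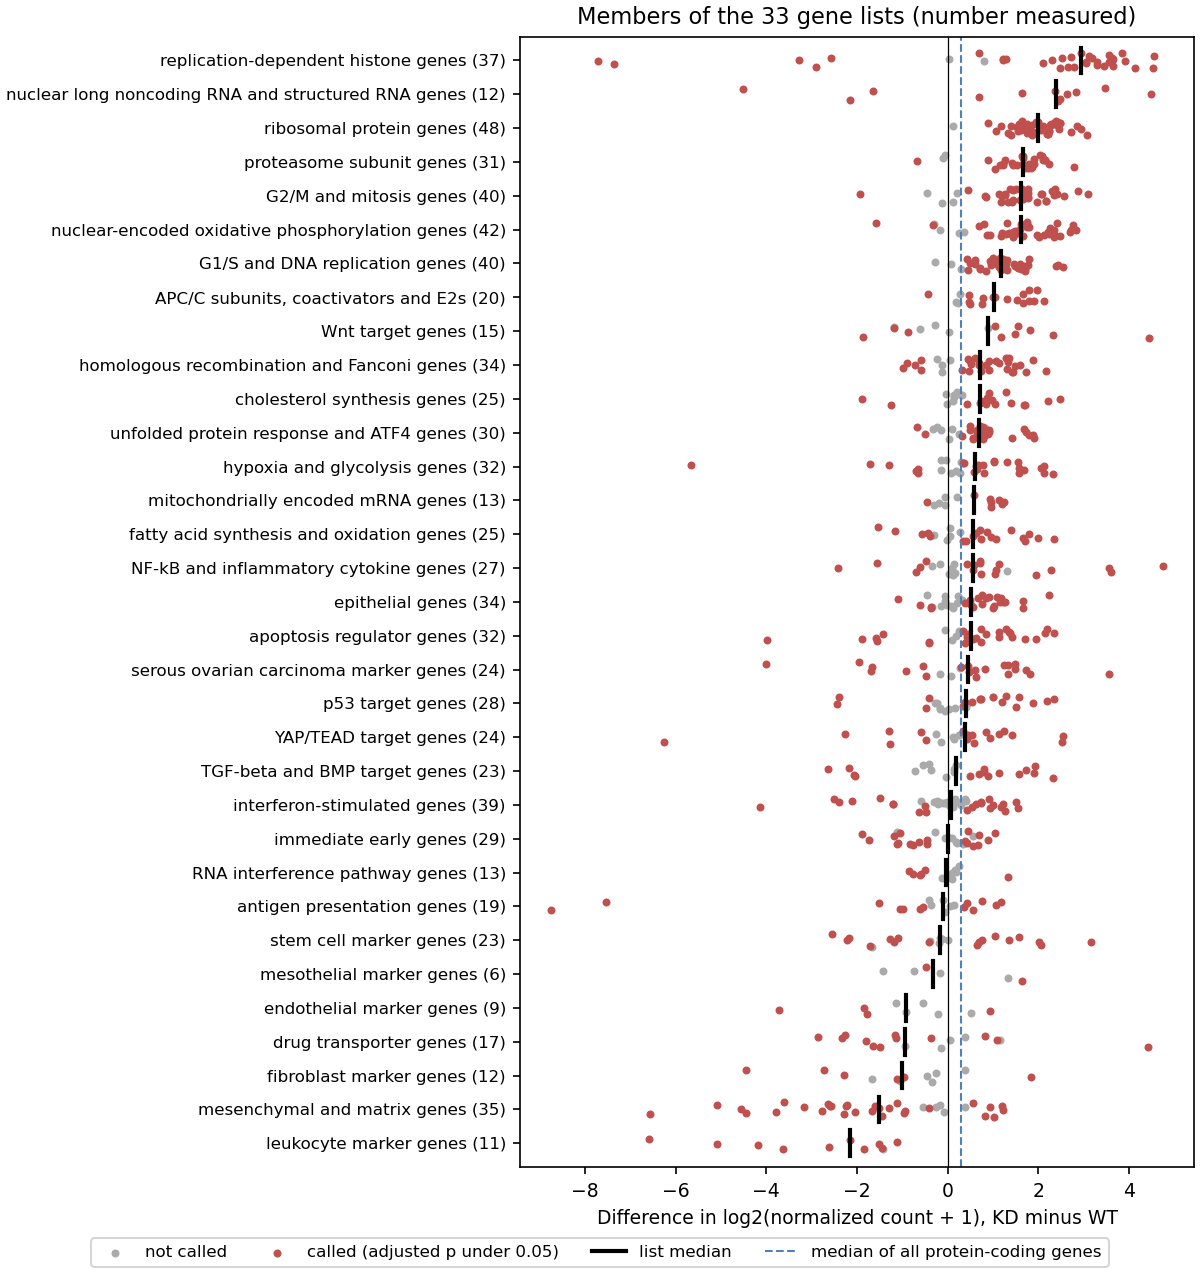
Difference in log2(normalized count + 1) between knockdown and wild type for each measured member of the 33 gene lists, with the number measured in brackets. Points are genes (red, called; grey, not called), black bars are list medians and the dashed line is the median of all protein-coding genes (0.28). Histone and ribosomal protein genes have medians of 2.95 and 1.99, and leukocyte markers -2.15; with equal library totals all medians are lower, and those between 0 and 0.56 and that of Wnt targets turn negative.

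With an estimated correlation between genes no list was called, among them the 17 lists called higher and the 2 called lower with the preset correlation. The few residual degrees of freedom put a call nearly out of reach in this form of the test, so it does not decide between the lists. The unfolded protein response and leukocyte lists lost their calls too, although their estimated correlations were -0.032 and -0.05. The other lists called higher, each with examples, were those of cholesterol synthesis (14 of 25 higher and 2 lower, adjusted p = 3.67e-03, ACAT2 and IDI1), apoptosis regulators (20 of 32 and 7, 7.06e-03, CYCS and BID; median 0.50, or -0.06 with equal totals) and fatty acid metabolism (15 of 25 and 5, or 6 adjusted over the list alone, 0.0248, ME1 and PLIN2; median 0.56, or -0.01 with equal totals). These 3 lists lost their calls with a mean of at least 50 normalized counts (0.118, 0.167 and 0.334) and with protein-coding genes only (0.224, 0.317 and 0.524), and the last also with equal totals (0.138). The list of nuclear long noncoding and structured RNAs was split: 9 of 12 rose and 3 fell (median 2.40, adjusted p = 0.0316). The call was lost with TMM, upper-quartile and median-of-ratios scaling (adjusted p = 0.0594, 0.0632 and 0.077) and with a mean of at least 50 normalized counts (0.184). The small RNAs RNY1 and RNU4-2 were 22.4-fold and 7.06-fold higher and RN7SL1 stood at 175910 ± 23200 against 15792, and the long nuclear transcripts NEAT1, MALAT1 and KCNQ1OT1 were 22.1-fold, 4.29-fold and 2.90-fold lower. Lists of interferon-stimulated genes (13 higher, or 12 adjusted over the list alone, and 10 lower of 39), antigen presentation (6 and 7 of 19), immediate early genes (8 and 11 of 29), stem cell markers (9 and 8 of 23), Wnt targets (7 and 3 of 15), YAP/TEAD targets (13 and 6 of 24), TGF-beta and BMP targets (11 and 4 of 23), drug transporters (3 and 9 of 17) and the RNA interference pathway (1 and 5 of 13) were not called. Adjusted p for these lists lay between 0.165, for drug transporters, and 0.886. Drug transporters were called lower with a mean of at least 50 normalized counts (adjusted p = 0.012, median -1.15) and with protein-coding genes only (0.0467). With no filter, the interferon (0.0327), YAP/TEAD (5.89e-03), TGF-beta and BMP (0.0309) and serous carcinoma (5.99e-03) lists were called higher. ABCB1, the multidrug efflux pump, had 20.7 ± 5.53 normalized counts in knockdown and no read in WT (at least 6.21-fold higher). It was a weakly expressed member that went against the drug transporter list. The more abundant transporter genes ABCA1 and ABCC3 were 4.67-fold and 3.48-fold lower.

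These differences sit on a shift that involves most genes and separates gene types. Of 23344 genes tested, 7329 were higher and 8465 lower in knockdown (limma, adjusted p under 0.05), 4342 and 6907 of them by at least 2-fold. The median log2 difference was 0.28 over 14464 protein-coding genes and -1.65 over 8880 other genes. By gene type it was -1.10 for lincRNA, -1.55 for antisense genes, -2.14 for sense intronic genes and -2.22 for processed pseudogenes. Protein-coding genes took 96.3% ± 0.224 of the reads in knockdown and 92.3% in WT, and lincRNA genes 0.489% ± 0.049 and 2.67%. Among protein-coding genes the median fell with exonic length, from 0.73 in the fifth with the shortest exonic length to -0.10 in the fifth with the longest, and was higher at higher levels, from -1.16 in the fifth with the lowest mean to 0.86 in the fifth with the highest. Level was the mean over these same libraries, most of them knockdown. Part of the trend with level may therefore come from the sorting.

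**Figure D3:**
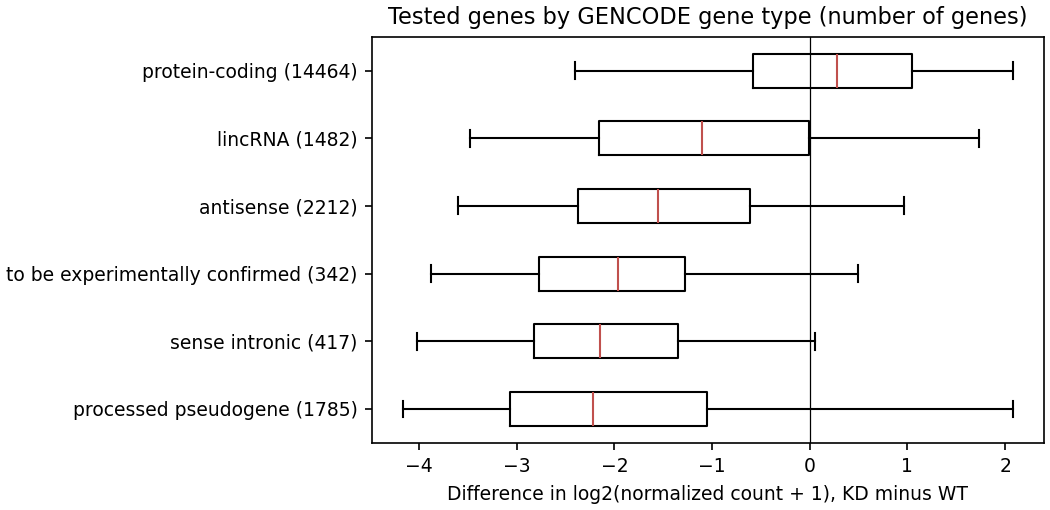
Difference in log2(normalized count + 1) between knockdown and wild type for tested genes by GENCODE gene type, with the number of genes in brackets. Boxes span the quartiles with the median in red and whiskers the 5th to 95th percentiles; protein-coding genes have a median of 0.28 and processed pseudogenes of -2.22, and the protein-coding median is -0.29 with equal library totals.

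The split of calls depends on the scaling between libraries: 46.4% of the called genes were higher in knockdown with the deposited factors, 27.0% with equal library totals and 56.8% with median-of-ratios factors from these 4 libraries, and the median of all tested genes was -0.28, -0.89 and 0.02. With 1 wild-type library the test rests on the assumption that it varies like the knockdown libraries, and any feature of that library or its preparation cannot be separated from the knockdown.

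Around ANAPC1P2 on chromosome 2, within 1 Mb, the coding neighbours went both ways. Only some of the measured neighbours are given here. MRPL35, a mitochondrial ribosomal protein gene (86199355 to 86213794 in GENCODE 29), had 4491 ± 572 normalized counts against 1042 in WT (log2 difference 2.10), and RMND5A (86720173 to 86778041) 8815 ± 326 against 3328. POLR1A, the largest subunit of RNA polymerase I (86020216 to 86106155), stood at 4855 ± 342 against 6471 (log2 difference -0.42), and PTCD3 at 3803 ± 140 against 3757. The measured coding genes nearest to ANAPC1P2 were the duplicated genes RGPD1 and PLGLB1. RGPD1 (86907953 to 87013976) overlaps ANAPC1P1, and PLGLB1 (87002559 to 87021852) lies between ANAPC1P1 and ANAPC1P2. They had 9.29 ± 8.20 and 12.1 ± 2.76 normalized counts against 24.4 and 52.2 (log2 differences -2.07 and -2.05).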

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

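The tests of protein-coding genes only, of scaling by median of ratios of these 4 libraries and of thinned knockdown reads were chosen after the data were seen. The counts of 7329 genes higher and 8465 lower in knockdown stayed within 1.5 times of these values under most alternatives, with these exceptions. Equal library totals gave 4701 higher and 12735 lower, with 2119 at least 2-fold higher. A mean of at least 50 normalized counts gave 5086 lower, 3340 of them at least 2-fold, and 8 lists called higher, with 15635 genes tested in place of 23344. Protein-coding genes alone, with TMM scaling among them, gave 4869 lower, 2788 at least 2-fold higher, 2869 at least 2-fold lower and 7 lists called higher, with 14514 genes tested. The cause of the change in list calls was not tested. With an estimated correlation between genes, 0 lists were called higher and 0 lower, against 17 and 2, but few residual degrees of freedom made such calls hard to reach. edgeR's quasi-likelihood test on the recovered reads called 7973 genes higher and 8514 lower, and DESeq2 7833 and 6016. Of the 15794 genes called by limma, edgeR also called 15425 and DESeq2 13164. Leaving out 1 knockdown library at a time gave 6500 to 6850 higher and 7118 to 7962 lower genes. ANAPC1P2 kept its direction, with a log2 difference from -2.42 to -0.77 when a knockdown library was left out, the last without KD 1. The leukocyte list was lost with a mean of at least 50 normalized counts, where drug transporters were called lower. No called list changed its direction in camera, and of 526 comparisons of lists under alternatives 46 lost and 10 gained a call. Among the genes selected for naming, 7 called higher in knockdown turned lower with equal library totals, which lowers all knockdown values relative to WT. Their log2 differences there were -0.18 for DUSP1, -0.11 for JUND, -0.081 for ANAPC1, -0.13 for PDIA3, -0.14 for JUN, -0.01 for HLA-C and -0.20 for HLA-E. In 273 of 4204 comparisons a named gene lost its call, and ANAPC2, CDH1, NDUFA10 and PSMA2, lower in knockdown, lost theirs with TMM, upper-quartile and median-of-ratios scaling and with DESeq2. Thinning the knockdown reads to the wild-type depth left 7116 genes higher and 7537 lower, and the gap between the medians of protein-coding and other genes was 1.94 to 1.97 in 20 draws, against 1.94 with all reads, so lower depth does not account for it. No paired analysis was possible because the wild-type group has 1 library. The ANAPC1P2 counts of 19 reads over knockdown and 14 in WT limit what depth can show about the depletion itself.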

Other observations

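The comparisons of read density with host gene level, of the leukocyte list with matched lists and of abundant with other neutrophil genes, the division of the called lists into groups and the marker genes of blood cells, Schwann cells and melanocytes and HLA genes were chosen after the data were seen. Of 16 red blood cell genes, 15 had a higher value in WT than the knockdown mean, though HBD, HBM, HBG1 and AHSP had only 3 or 4 reads there, and HBG2 had 43 reads in knockdown and 0 in WT. Besides HBB, HBA1 and HBA2, the wild-type library held 305 normalized counts of ALAS2, the erythroid enzyme of heme synthesis, 160 of SLC4A1, the anion exchanger of the red cell membrane, and 185 of TRIM58, against 1.26 ± 2.19, 0 and 0 in knockdown. Of 11 neutrophil genes 10 had a higher value in WT, with CSF3R at 22.2 ± 6.52 against 485 and MNDA at 0 against 124, and S100A12 had 22 reads in knockdown and 4 in WT. Of 11 Schwann cell and melanocyte genes 9 had a higher value in WT, with SOX10 at 4.94 ± 3.96 against 860 and MLANA at 124 ± 36.3 against 671, and FOXD3 and TYR a lower one. Of 13 HLA and class II pathway genes 10 had a higher value in WT, and HLA-C, HLA-E and HLA-DRA a lower one (HLA-C and HLA-E turn with equal library totals). Since these genes were picked after their values were seen, the counts describe the libraries and test nothing. KLK3, which encodes prostate-specific antigen, had 136 normalized counts in WT and 0 reads in knockdown, and was also chosen after its values were seen.

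PAX8, the Müllerian transcription factor and a member of the serous carcinoma list that fell in knockdown while the list's median was above 0, had 19884 ± 1521 normalized counts in knockdown and 62685 in WT (limma adjusted p = 1.40e-04). Its antisense transcript PAX8-AS1 had 6047 ± 1187 and 73330, and counting that ignores strand would not tell the pair apart where they overlap. WT1, also a transcription factor gene of the ovarian serous lineage, had 2048 ± 258 against 2281 and was not called (adjusted p = 0.364). PAX8-AS1 and WT1 were chosen after their values were seen.

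Genes that are not protein-coding were higher in the wild-type library in the median, with a log2 difference of -1.65. Not every type followed, as the 10 genes of small Cajal body RNA (scaRNA) had a median of 0.576. Noncoding genes inside introns of expressed genes had an excess of 2.28 reads per kb of exon per 1e6 protein-coding reads in WT on the host's strand and 2.79 on the opposite strand, against 0.032 in intergenic noncoding genes. Genomic DNA in the wild-type library would raise intergenic genes alike, and the ratio of intergenic to same-strand excess was 0.014 (95% bootstrap interval 0.012 to 0.017), which argues against it. A larger share of unspliced or nuclear RNA was to show as more excess on the host's strand, and the ratio of 0.817 (0.743 to 0.899) met the bound set beforehand against it, an upper limit under 1, but that bound presumed counting by strand, and densities on the host's and the opposite strand were near each other in every library (0.388 and 0.421, 0.482 and 0.533 and 0.323 and 0.319 in KD 1 to 3, and 2.74 and 3.30 in WT, where the gap was widest), as when counting ignores strand, so the ratio decides nothing. Opposite-strand excess was larger where the host gene was more abundant (Spearman's rho across 2346 genes, which are not independent replicates, 0.41, interval 0.373 to 0.446), so intron RNA of expressed genes counted without regard to strand is a candidate source, and whether the knockdown or the preparation of 1 library changed it stays open.

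Lists of short, abundant mRNAs were higher in knockdown, while the median difference of all protein-coding genes also varied with exonic length and level. Against 10000 random protein-coding lists matched on both, 5 of the 16 called lists of protein-coding genes lay in the upper 2.5%. Fewer than the majority was the outcome set beforehand for length and level as the source. The ribosomal protein, oxidative phosphorylation, proteasome, G2/M and histone lists were these 5, grouped after the data were seen, with a lowest percentile of 99.84. That value follows from the grouping. The random lists also drew genes singly, while members of these lists varied together (estimated correlation 0.404 to 0.889). Their medians were above those of nearly all matched lists, but this does not exclude length and level as the source. The other 11 called lists, the G1/S and APC/C lists among them, reached at most 93.88, and the epithelial list lay at 0.15. The calls of these 11 lists may therefore come from the trends with length and level, the latter measured on the same libraries that are compared. The knockdown itself, and a difference in RNA or library preparation that acts on these genes in some other way, stay open as untested.

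Leukocyte markers were higher in the wild-type library, as weakly expressed protein-coding genes were in general, with level taken as the mean over these same libraries. The list's median lay at percentile 2.72 of 10000 protein-coding lists matched on mean expression, and at 2.18 when exonic length was matched too. The exact 95% interval of the first, 2.41 to 3.06, covers the random draws only, not the spread of the 11 genes or of the wild-type library. The interval spans the bound of 2.5, and the 2 percentiles lie on either side of it. A general shift of weakly expressed genes therefore cannot be told apart from a separate change of these 11 genes. RNA of blood cells in the wild-type library is a further candidate source, and would bring S100A8 and S100A9, very abundant in neutrophils, which stood at 47.9 ± 12.8 and 277 ± 11.4 in knockdown and 98.9 and 492 in WT (4 of the 11 neutrophil genes had a knockdown mean of at least 10). The median excess of S100A8, S100A9 and S100A12 was 0.41 of that of FCGR3B, CXCR1, CXCR2, FPR1 and MNDA (0.68 when multiplied by 1.66, the median fold by which the shortest protein-coding genes were lower in WT), but the genes moved apart, with ratios of -0.02 for S100A12, 0.41 for S100A8 and 1.73 for S100A9, so this source is neither excluded nor shown, and RNA of other cells or samples, untested for the globin, SOX10, KLK3 and mesenchymal genes, stays open for their higher values in WT.

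Taking each library in turn as the lone one gives only 4 splits, too few for a share under 0.05. With a knockdown library alone, WT, the most distant library, falls in the group that gives the spread. Few calls were thus to be had in those splits from the start, so the contrast below decides nothing about the grouping. WT as the lone library gave 15794 called genes, the most in 1 of 4 splits, and the highest of the other splits gave 0 (limma; 43 at an unadjusted p under 0.05 for KD 3, 10 for KD 1 and 1 for KD 2).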
